A study of Homo sapiens with 6 samples.

How the data were processed

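Genomic DNA of CAL-62 cells was sequenced as untreated input and after a chemical pull-down of 5-formyluracil, with library preparation at pH 7.2 or pH 8.8, in 2 libraries each, per the labels. Trim Galore, Bowtie2, MACS2 2.2.6 and the human build hg38 are named in the submitters' processing notes. What each tool did, and how sites were called, is not given in the sources used here.

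The deposited counts are the coverage and the number of C reads at each site in each of the 2 pH 8.8 libraries, per the file headers. The deposited fraction is the C reads divided by the coverage, per the file headers, and it matched the counts at all 967 sites in both libraries to within 1e-09. A second deposited table held the same 967 sites, and only its positions, strands and reference bases were used; its 10 number columns per library have no header and were not used. The values lay within limits of at least 10 reads, at least 3 C reads, and a fraction above 20% and below 50%. These limits were read from the values and are taken here as the filter, which is not given in the sources used here.

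Libraries were grouped by the labels. The planned tests of pH 8.8 against pH 7.2 and against input were not run, since the values used are those of the pH 8.8 libraries. Levels over both libraries are the summed C reads over the summed coverage with 95% Wilson intervals, and a mean ± SD is over the 2 libraries. A level common to all sites was fitted by maximum likelihood to a binomial truncated at the table's limits. A beta spread of levels was added to that fit, shared by both libraries or separate in each, and the gain of each form was compared with 100 tables simulated with a single level. The gain of the separate form over the shared form was compared with 100 tables simulated with shared levels, at the fitted spread and at the lower end of its interval. Agreement between libraries was measured across sites with 100000 permutations.

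No genome sequence was used here, so the planned random T positions were replaced by random positions between the first and the last annotated gene of each chromosome, matched on chromosome, in 10000 draws. That choice, the exclusion of stretches of over 500 kb without a gene, the background of sites moved by 50 to 500 kb, the distances of 50 bp and 100 kb, the comparison of close pairs with pairs of similar coverage (within 2 reads in each library, or the 5 nearest sites where fewer were that close), and the tie rule for genes (total coverage) were made after seeing the data. Genes came from the RefSeq table of the same build, which gives a start and an end for each of 59679 genes but no strand or exons. Sites were assigned in order to protein-coding genes, non-coding RNA genes, other genes, the 1 kb around a gene, and intergenic sequence, and tests over these 5 classes were adjusted by Benjamini-Hochberg. Chromosomes were tested with 100000 draws and by exact binomial tests. The Monte Carlo test of the chromosomes and the comparison of likelihood gains use the upper tail, the other Monte Carlo tests are two-sided, and those that place the sites anew at random or by moving them are called permutation tests.

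The groups, tests, 7 gene lists and the rule for named items were fixed before the data were examined. That rule names the 10 sites with the largest measure (ties by higher coverage, then by chromosome and position), the 10 genes with most sites, every list member with a site and the 5 densest windows of 10 kb. The site of 1 list member is not reported here. No site lay on the mitochondrial genome. Besides the 7 lists, 2 gene groups were counted that were drawn up after the genes with a site had been seen. The DNA repair group had 13 of 174 genes with a site against 3.67 expected from random positions and 6.91 from moved sites, but some of its members were put in because they held a site, so its count is no evidence. The genes named ZNF had 7 of 517 against 14.7 expected and 10.4 from moved sites (permutation p = 0.0328 and p = 0.295).

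The calculations were tested on simulated data for the same 967 sites. The level fit recovered 4 of 4 simulated levels within its interval. The spread fit gave 5 points for a simulated spread of 5 points, and 2.5 points where the simulated spread was 0, so a fitted spread is judged only against simulated tables. Without the table's limits, the Fisher test recovered 162 of 200 sites simulated at 15% against 75%, with 2 false calls; within the limits, at 15% against 45%, it called 0. Of 200 sets of random positions, 14 (7.0%) passed the threshold of 0.05 for the share in genes, and 97 sites planted in genes were detected (permutation p = 0.0410). Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.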

Results

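The series asked where 5-formyluracil, an oxidation product of thymine, lies in the genome of CAL-62, an established human thyroid carcinoma cell line. Genomic DNA was sequenced without treatment (input) or after a chemical pull-down that tags the formyl group of the base with an azide-bearing reagent. Pull-down libraries were prepared at pH 8.8, where the modified base is read as C, or at pH 7.2, where it is read as T. Each of the 3 groups has 2 libraries, 6 in all. The values analysed here are those of the 2 pull-down libraries prepared at pH 8.8, and values of the other 4 libraries were not analysed here. A site is therefore a thymine with C reads in both pH 8.8 libraries, and its background in input and at pH 7.2 was not analysed here.

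The first question was which thymines were read as C, and how often. The table held 967 sites, 488 with a reference T on the plus strand and 479 with a reference A there, which is a T of the minus strand. The mean share of reads with C was 28.8% ± 6.70 (SD over sites) in library 1 and 30.0% ± 6.73 in library 2, and the mean of the 2 libraries was 29.4% ± 0.848 (SD, n = 2). Ordered by the share over the summed reads of both libraries, the first site (46.9%) lay outside any annotated gene at position 88998123 of chromosome 16 (46.5% ± 1.53, SD, n = 2, 32 reads). Next in that order came sites in HS3ST4, which encodes a heparan sulfate sulfotransferase (chromosome 16, position 25807221, 45.9% of summed reads, mean of libraries 45.8% ± 0.494), and in FARS2, the mitochondrial phenylalanyl-tRNA synthetase (chromosome 6, position 5261368, 45.7% of summed reads, mean of libraries 44.0% ± 5.66).

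The other named sites of high share are given with their means over the 2 libraries. The site in the kinase gene MAP3K19 (chromosome 2, position 135013148) had 45.4% ± 0.589 over 44 reads. TCOF1, which encodes a nucleolar protein of ribosome biogenesis, had 44.6% ± 1.21 at position 150394699 of chromosome 5. ULK1, a kinase that starts autophagy, had 44.2% ± 3.54 at position 131904344 of chromosome 12. The nucleolar GTPase gene GTPBP4 had 42.2% ± 3.14 at position 1005336 of chromosome 10. SHC2, a signalling adaptor gene, had the widest gap between libraries among these sites, with 48.3% in library 1 and 30.8% in library 2 at position 439871 of chromosome 19. The 2 remaining sites, at positions 73843618 and 59387503 of chromosome 15, lay outside annotated genes and had 43.7% ± 1.12 and 42.7% ± 1.47. The last 3 of the 10 (SHC2, GTPBP4 and position 59387503) were taken from 5 sites tied at 42.9% of summed reads, by coverage and then by chromosome and position. The tied sites left out by that order, in SMIM36 (chromosome 17, position 55530525) and at position 75929628 of chromosome 16 outside annotated genes, are named after their values were seen. These 10 sites had 27 to 44 reads over both libraries, and the 95% Wilson interval of the first ran from 30.9 to 63.6%. Their order within the 10 was therefore not resolved at this depth. The intervals of TCOF1, ULK1, SHC2, GTPBP4 and the 2 sites of chromosome 15 also held the mean over all sites (29.14%). With every share below 50% in each library, a share this high over summed reads needs high shares in both. A small SD between libraries is therefore partly set by how these sites were chosen.

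Coverage was 17.4 ± 6.06 reads per site in library 1 (10 to 45, 16795 reads in all, 4748 of them C) and 15.3 ± 4.87 in library 2 (10 to 48, 14756 reads, 4357 of them C). Each value in the table had at least 10 reads, at least 3 C reads and a C share above 20% and below 50%. At 495 sites (51.2%) in library 1 and 463 (47.9%) in library 2, the C reads were at the lowest number these limits allow for the coverage. Fitted with the limits taken into account, a single level for all sites was 20.2% (95% interval 19.2 to 21.2) in library 1 and 22.1% (20.9 to 23.1) in library 2. Fits that allow levels to spread were better. Their mean was 16% (95% interval 10 to 19) for levels shared by the libraries and 15% (11 to 18) for spread separate in each. Those are means of levels before the limits act, not of the listed sites, and are not directly comparable with the single level. The median Wilson interval of a site over both libraries was 30.1 percentage points wide, and it held 20% at 820 sites (84.8%) and 50% at 249 (25.7%). PCR reads are not independent molecules, so these intervals cover counting error only, and nothing in the labels says that the 2 libraries came from separate cultures.

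**Figure D1:**
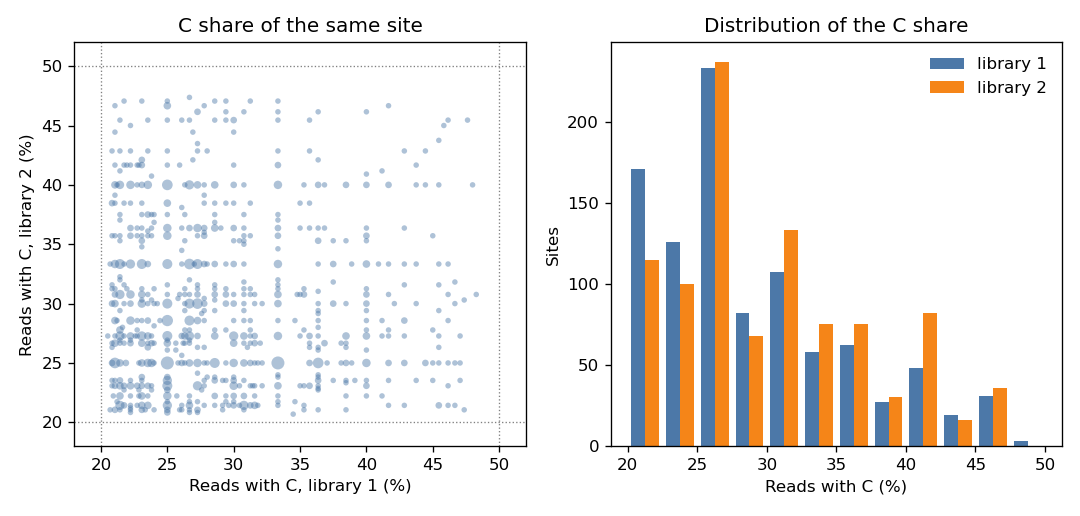
Left, the share of reads with C (%) at each of the 967 sites in library 1 (x axis) and library 2 (y axis) of the pH 8.8 pull-down, with larger points where several sites coincide and dotted lines at 20 and 50%. Right, the number of sites by share of reads with C (%) in each library; most sites lie near the lower limit, and no agreement between libraries was detectable within the limits (r = -0.00551).

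Whether the 2 libraries ranked the sites alike was asked next. They did not do so detectably: across the 967 sites, the C shares had a Pearson r of -0.00551 (permutation p = 0.863, adjusted p = 0.863) and a Spearman rho of -0.0137 (permutation p = 0.670, adjusted p = 0.670). Coverage had an r of 0.140 (permutation p = 2e-05, adjusted p = 6e-05), and the number of C reads had an r of 0.0828 (permutation p = 0.0103, adjusted p = 0.0154). These were 3 measures across sites, which are not independent replicates. Within the limits of the table, an r near 0 does not settle agreement. Tables simulated with levels shared by the libraries, at the fitted spread, had a mean r of 0.0694 (range 0.00611 to 0.135). The observed r of -0.00551 lay below that range. At the lower end of the spread, the mean was 0.0413, and the range (-0.0180 to 0.0987) held the observed r. A fit with spread separate in each library gained 13.2 in likelihood ratio over shared levels. Tables simulated with shared levels gave at most 5.53. The two-sided Fisher exact test between libraries called 0 sites at an unadjusted p under 0.05 and 0 after Benjamini-Hochberg adjustment. That test had no power here: with simulated shares of 15% against 45% at 200 of the 967 sites, kept within the same limits, it also called 0.

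The distribution over chromosomes asked whether sites follow genome length. Chromosome 19, the most gene-rich, had 84 sites, or 1.43 per Mb of annotated length against 0.313 over all chromosomes, a ratio of 4.58 to the number expected from length. Chromosome 20 had 63 sites (ratio 3.13), chromosome 17 had 57 (ratio 2.19) and chromosome 16 had 57 (ratio 2.02). Chromosome 4 had 5 sites (ratio 0.0839), chromosome 13 had 3 (ratio 0.0838), chromosome 18 had 5 (ratio 0.199), chromosome X had 11 (ratio 0.225) and chromosome 1 had 45 (ratio 0.577). The chi-square statistic over 24 chromosomes was 620 (Monte Carlo p = 1e-05, the smallest that 100000 draws can give). In exact binomial tests with Benjamini-Hochberg adjustment, 7 chromosomes had more sites than their length predicts and 8 had fewer. Against the number of annotated genes per chromosome, 7 had more and 9 fewer.

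Site density rose with gene density. Across chromosomes 1 to 22 and X (23 in all), sites per Mb and genes per Mb had a Pearson r of 0.870 (permutation p = 2e-05, adjusted p = 6e-05) and a Spearman rho of 0.781 (permutation p = 3e-05, adjusted p = 9e-05). Without chromosomes 19 and 17, the r was 0.706 (permutation p = 0.000310) and the rho 0.717 (permutation p = 0.000380). Of the 3 relations computed, those with mean site coverage (rho 0.260, permutation p = 0.229, adjusted p = 0.229) and with mean C share (rho -0.312, permutation p = 0.147, adjusted p = 0.221) did not pass the threshold. Both strands carried sites alike: 50.5% lay on the plus strand (exact 95% interval 47.3 to 53.7, exact binomial p = 0.797).

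**Figure D2:**
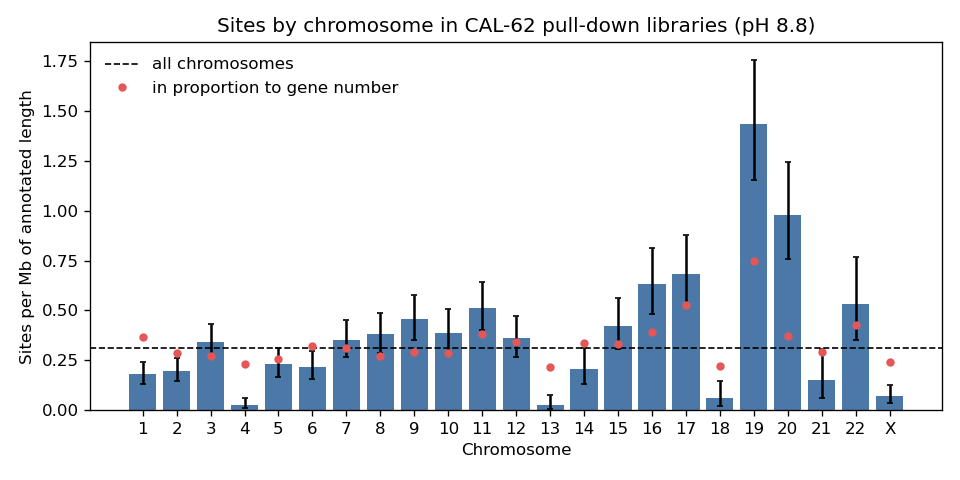
Sites per Mb of annotated length for chromosomes 1 to 22 and X, with exact 95% binomial intervals of each chromosome's share of all sites. The dashed line is the density over all chromosomes (0.313) and red points are the density expected from the number of genes. Chromosome 19 stands highest at 1.43 and chromosomes 4 and 13 lie near 0.

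The place of the sites relative to genes was compared with random positions of the same chromosomes, in permutation tests that place the sites anew at random. Of the 967 sites, 637 (65.9%) lay in an annotated gene, against 57.3% of random positions, a difference of 8.61 percentage points (permutation p = 0.0002, the smallest that the draws can give). Protein-coding genes held 542 sites (56.0% against 44.3%, adjusted permutation p = 0.0005) and 39 lay within 1 kb of a gene (4.03% against 2.39%, adjusted p = 0.00475). Genes of long non-coding RNAs alone held 80 (8.27% against 11.3%, adjusted permutation p = 0.0040), and 291 were intergenic (30.1% against 40.3%, adjusted p = 0.0005). Sites were assigned to protein-coding genes first, so an excess there leaves fewer for later classes, and these deficits are not separate results. Pseudogenes and other genes held 15 (1.55% against 1.69%, adjusted permutation p = 0.868). On average, 34.5 annotated genes lay within 500 kb of a site, against 23.4 around random positions (95% range 22.3 to 24.4). With stretches of over 500 kb without a gene left out, 61.9% of random positions lay in a gene. The excess of the sites fell to 4.01 points (permutation p = 0.0094). The excess in genes ended when the sites themselves, moved by 50 to 500 kb, were the background. Of the moved sites, 68.3% lay in a gene, a difference of -2.39 points (permutation p = 0.0900). The calls for protein-coding genes (57.6% of moved sites, adjusted permutation p = 0.388), the 1 kb around genes (3.23%, 0.388), non-coding RNA genes (8.63%, 0.727) and intergenic sequence (28.5%, below the 30.1% of sites, 0.388) ended there as well. Exon, intron and UTR were not analysed here.

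**Figure D3:**
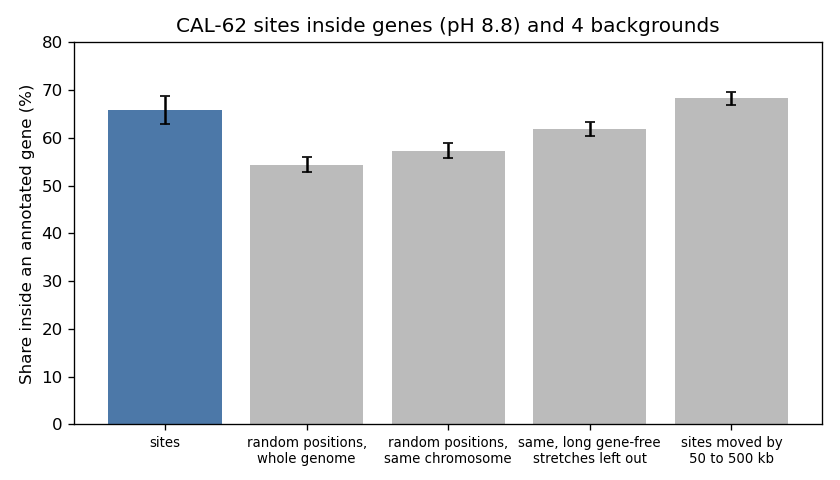
Share of positions inside an annotated gene (%), for the 967 sites (blue, 95% Wilson interval) and for 4 backgrounds (grey, mean and SD of 10000 draws). The sites stand at 65.9%, above 57.3% for random positions of the same chromosomes and below 68.3% for sites moved by 50 to 500 kb. Random positions with long gene-free stretches left out stand at 61.9%.

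In all, 646 genes held a site, 513 of them protein-coding and 111 of long non-coding RNAs. A single site was held by 593 genes, 2 sites by 51 and 3 sites by 2. ABR (chromosome 17, 1003519 to 1229722) held sites at positions 1017577, 1093243 and 1144709 with C shares of 22.5% ± 1.49, 31.5% ± 5.31 and 25.9% ± 6.37 (SD, n = 2). VWF, the gene of the clotting protein von Willebrand factor (chromosome 12, 5948877 to 6124670), held 3 sites between positions 6121701 and 6121729, with 26.8% ± 2.53, 23.2% ± 2.53 and 28.3% ± 10.5.

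The other genes named for their number of sites held 2 each. RAD18, a ubiquitin ligase of post-replication repair, held sites at positions 8902980 and 8902983 of chromosome 3 on opposite strands (25.4% ± 0.570 and 24.9% ± 3.32). LRFN2, a synaptic adhesion gene, held sites at 40474737 and 40474741 of chromosome 6 (22.2% ± 1.91 and 32.9% ± 3.44). A pair at 157381580 and 157381582 of chromosome 3 lay in both VEPH1 and the overlapping non-coding gene LOC101928236 (30.5% ± 9.88 and 31.4% ± 2.77). The non-coding genes LINC00671 (chromosome 17) and LOC105374831 (chromosome 2) held pairs at 42893840 and 42893847 and at 82833825 and 82833834. Sites far apart in the same gene were found in TRAPPC9, a subunit of a vesicle tethering complex (chromosome 8, positions 139830351 and 140356759), and RANBP10 (chromosome 16, positions 67738373 and 67776394). Of the 53 genes with more than 1 site, 21 held them all within 50 bp.

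Gene lists chosen for a thyroid carcinoma line and an oxidised base were set against random positions. Among 18 thyroid differentiation genes, 1 held a site: TG, the thyroglobulin gene, at position 133091504 of chromosome 8, where SLA overlaps it (32.5% ± 10.6, SD, n = 2). Among 22 thyroid cancer drivers, 3 held a site, among them TERT, the telomerase reverse transcriptase gene (chromosome 5, position 1269431, 24.3% ± 1.04), and NTRK3, a receptor kinase gene (chromosome 15, position 88152249, 37.9% ± 3.03). Among 20 genes of oxidised pyrimidine repair and demethylation, UNG, the uracil glycosylase gene, held a site (chromosome 12, position 109104316, 32.8% ± 2.84). Neither the thyroid differentiation list (1 against 0.546 expected, adjusted two-sided permutation p = 1), nor the drivers (3 against 0.856, p = 0.321), nor the repair list (1 against 0.257, p = 1) passed the test, adjusted over the 7 lists.

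The common fragile site genes held fewer sites than random positions of their chromosomes. Of 22 such genes, which are mostly very long, 2 held a site against 8.27 expected (95% range 4 to 12, adjusted permutation p = 0.0126): RBFOX1 (chromosome 16, position 6926294, 39.1% in library 1 and 23.5% in library 2) and CNTNAP2 (chromosome 7, position 148158339, 25.9% ± 2.96). The call ended among the 487 sites of higher C share (ratio 0.200, adjusted permutation p = 0.284). It also ended when sites moved by 50 to 500 kb were the background (ratio 0.637, adjusted permutation p = 1). Every such move leaves the RBFOX1 site inside its gene, and most leave the CNTNAP2 site inside its own. Moved sites could therefore hardly show a deficit in this list, and that outcome does not argue against one. No site lay in the 20 centrosome and cell cycle genes (0.258 expected), the 23 MAPK and PI3K signalling genes (0.875 expected) or the 16 oxidative stress genes (0.173 expected), each with an adjusted p of 1. Over all 141 genes, 7 held a site against 11.2 expected (permutation p = 0.140).

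The spacing of the sites was compared with random positions as well. A neighbouring site within 1 kb was found for 91 sites, against 0.964 expected (permutation p = 0.0002, the smallest that the draws can give), and within 50 bp for 83, against 0.0530 expected. The densest window of 10 kb was the VWF window on chromosome 12, with 3 sites over 29 bp. Next by coverage came windows of 2 sites on chromosome 20 (positions 58941210 and 58941213, outside annotated genes), in LINC00671, in LOC105374831 and in RAD18. The 42 pairs within 50 bp had a median distance of 6.5 bp, and 23 (54.8%) lay on the same strand (exact 95% interval 38.7 to 70.2, exact binomial p = 0.644). The C reads of both members were equal in both libraries in 26.2% of these pairs, against 10.7% of pairs drawn from other sites of similar coverage (95% range 2.38 to 21.4, permutation p = 0.0050), and within 1 read in 69.0% against 47.6% (permutation p = 0.0074). Members of a pair lie within 50 bp and can be covered by the same reads, so their counts cannot be taken as independent. Shared reads were not examined.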

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

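Backgrounds without long gene-free stretches or of moved sites, the distances of 50 bp and 100 kb, gene number as the expectation for chromosomes, and the agreement settings were chosen after seeing the data. The share of sites in genes kept its direction and its side of the threshold under 6 of 7 alternatives that can change it (4.01 to 11.7 points) and turned to -2.39 against moved sites, where the ratio over all lists turned to 1.01 (permutation p = 1). The number of neighbouring sites moved to 245 at 100 kb (91.0 expected, 177 from moved sites), to 30 among the 487 sites of higher level (0.241 expected), and to 0 with 1 site per cluster, which is 0 by construction. The share on the plus strand, never past the threshold, was 49.7% among those 487 and 49.9% without chromosome 19. The mean level was 27.4% at a minimum of 20 reads (54 sites), 33.0% among those 487, by construction, and 28.8 to 30.0% without each replicate in turn. The lowest share that the limits allow tends to be higher at low coverage, so a lower mean at 20 reads can follow from the limits. How much of the shift they make was not tested. The r between libraries turned to 0.196 at 20 reads (permutation p = 0.156) and to 0.00634 with 1 site per cluster (p = 0.847); the cause was not tested. The uneven chromosome distribution held under 5 of 5 such alternatives. The call of the fragile site genes ended under 2 of 8 alternatives, among them the moved sites, which could hardly show a deficit there. The other lists, with few sites expected, say nothing on stability. A flank of 2 kb leaves the share in genes as it is by construction, and moved the sites beside genes from 39 to 72 and intergenic sites from 291 to 258. The tables hold the same sites and a minimum of 5 reads removes none, so those alternatives test nothing. Not run were backgrounds matched on T or GC content, chromosome length without N, sequence context, repeats, promoter and exon classes, the authors' annotation, enrichment, overlap within 5 or 100 bp between replicates, and site sets without a replicate. No paired analysis was possible because the values used are those of the pH 8.8 libraries alone. Depth of 10 to 48 reads per value limits every statement on a single site.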

Other observations

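The fits of spread between levels, the bounds for counting error, for levels shared by the libraries, for chance placement and for strands, and the test of gene density as the whole cause were chosen after the results were seen. The tests of an inherited difference, of a low error rate, of a second copy, of gene density and of coverage were set before.

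The C shares lay just above the lower limit and did not rank alike in the libraries detectably. An inherited T/C difference on 1 of 2 copies at every site would need a level near 50%. A single-level fit over both libraries together gave 21.05%, with an upper bound of 21.75%. The upper bounds of the fits of each library were 21.2% (library 1) and 23.1% (library 2). A single error rate below 10% lies under the lower bound of the fit over both libraries (20.3%). It also lies under the lower bounds of the fits of each library (19.2% and 20.9%). A rate that varies between sites stays open, since the mean before the limits reaches down to 10% with shared spread. Counting error around a single level is argued against, for independent reads, by the gain of a fit with spread. That gain was a likelihood ratio of 13.2, against at most 5.73 in 100 simulated tables. Simulated reads were independent, while PCR reads are not independent molecules. Neither this gain nor the next therefore excludes a single level. Spread beyond counting error that is separate in each library gave a larger gain (26.4, against at most 9.37 in tables with a single level) and is a candidate explanation; its gain over shared levels was 13.2, against at most 5.53 in tables simulated with shared levels, and shared levels stay open as part of the spread, since the r of -0.00551 lies below the range at the fitted spread (0.00611 to 0.135) but inside that at its lower end (-0.0180 to 0.0987). No biological explanation was tested. An inherited difference at some of the sites stays open, as does a difference on less than 1 of 2 copies, which the test above does not address.

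Sites within 50 bp of each other, as in VWF and RAD18, numbered 83. Chance placement would give 0.0530. Several modified thymines on a single strand as the whole cause would put nearly all pairs on the same strand, and 54.8% were (upper bound 70.2%), so that explanation is left only for the 23 same-strand pairs. Reads from a second copy of the sequence cannot be told apart from other causes. With 1 site taken per cluster, 5.56% of 18 sites in coding genes lay in a gene with a named pseudogene. Random positions gave 8.68%, and the sites are too few to decide. The only such gene among them was VWF, which also holds the densest window. Whether its pseudogene copies the stretch that holds those sites was not examined. No biological explanation was tested.

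Site density differed between chromosomes, from 1.43 per Mb on chromosome 19 to 0.0263 on chromosomes 4 and 13 among the autosomes. Gene density may account for part of it (rho 0.781). As the whole cause it is argued against by 16 of 24 chromosomes that departed from the number their genes predict, such as chromosome 20 with a ratio of 2.64 and chromosome 1 with 0.493. Copy number or depth of the chromosomes cannot be told apart from other causes (rho 0.260 with mean site coverage), because the table starts at 10 reads and holds coverage at sites alone. These relations take whole chromosomes, and density also varied within them. Chromosome 2, for example, had no site between positions 135657168 and 219429716. Such empty stretches were seen afterwards and were not tested. No biological explanation was tested.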
